A study of Streptococcus thermophilus with 3 samples.

How the data were processed

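Total RNA of wild-type LMD-9 and of the mecA knockout CB052 was measured on 3 two-colour Agilent arrays. Per the labels' protocols, precultures grown for 16 h at 37 °C in THB with 1% glucose were diluted 30-fold, 25 ml aliquots were taken at an optical density of 0.4, and cDNA was made from 10 µg of RNA and labelled with a green or a red Alexa Fluor dye. The labels place the knockout in red on arrays 1 and 2 and in green on array 3, the dye swap of array 2. Arrays 1 and 3 shared a slide, and array 2 was on another.

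The deposited scanner files hold spot intensity values, mean signal and median local background per channel, made with Agilent Feature Extraction 9.1 per the submitters' processing notes and 9.1.3.1 per the file headers. The same files hold processed intensity values, background-subtracted and dye-normalized, and a log10 ratio of red to green per spot, per the file headers. The deposited value table of the series is the same log10 ratio, with the column of array 3 turned in sign, so that every column is knockout over wild type; its columns have medians of 0, -0.0011 and 0. Scale, centring and direction of the table were thus settled by comparison with the scanner files.

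The intensity values were read with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50 on all spots, and ratios were normalized within each array by loess with a span of 0.3. The 536 control spots had weight 0 in loess and were then left out. Outlier-flagged spots, 30 on array 1, 335 on array 2 and 14 on array 3, were left out; saturated spots, 2 on array 2, were kept. The sign of array 3 was turned. A probe was kept if it was well above background in the knockout channel on all 3 arrays or in the wild-type channel on all 3 arrays, which kept 8256 probes and left out 154. Spots were averaged per probe and probes per locus tag. Arrays 2 and 3, made from the same RNA, were averaged before the fit.

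Each tag's mean log2 ratio over the 2 biological replicates was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the 1909 tags and a threshold of 0.05. The fit had 1 residual degree of freedom per tag and 5.0 prior degrees of freedom. Ratios for 1909 tags, of which 200 were changed, were simulated over 20 draws with the spread estimated here. The fit recovered 85.6% of tags changed by 1 on the log2 scale, 99.6% of those changed by 2 and 100% of those changed by 4. Of its calls, 6.17% were false. The simulated tags were independent, their spread did not grow with the change, and their dye noise cancelled when arrays 2 and 3 were averaged. These shares describe the simulation and may not hold for the arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

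Named tags were set before the data were examined as the called tags with the highest and lowest mean ratio and 1 sign on all 3 arrays. Only 2 that rose and 2 that fell are given, fewer than the plan set. Since the files do not pair tags with names, the mecA transcript, the genes beside mecA and the gene lists fixed beforehand, with their set tests, were not analysed here. Alternatives covered the background correction, the normalization, the filter, the summary over probes, Feature Extraction's processed signals, the deposited table, other models of the 3 arrays and leaving out each array. A fit with a slide term was added after the data were seen.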

Results

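Gene expression was compared between Streptococcus thermophilus LMD-9, a lactic acid bacterium used in dairy fermentation, and its mecA knockout, strain CB052. In streptococci, as in Bacillus, mecA encodes an adaptor protein that delivers other proteins to a Clp protease. Both strains were grown at 37 °C in THB medium with 1% glucose and harvested in mid-log phase at an optical density of 0.4. RNA of the knockout and of the wild type was labelled with different dyes and hybridised together, so that each of the 3 arrays gave the ratio of knockout to wild type within the array. Array 1 held biological replicate 1, array 2 held biological replicate 2, and array 3 held the RNA of biological replicate 2 with the dyes exchanged. Arrays 2 and 3 were therefore averaged, and every test rested on n = 2 biological replicates.

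Each array carried 15208 spots for 1923 locus tags, the numbered gene identifiers of the genome, with 8410 different probes of 60 bases. The files pair no locus tag with a gene name, so the probes for mecA itself could not be picked out and the loss of its transcript was not checked. After the filter on dim probes, 1909 tags were tested. The median spot signal was 1325 in green and 2579 in red on array 1, 5676 and 12269 on array 2, and 4943 and 6819 on array 3. Against the local background these medians stood 32.3-fold and 48.2-fold higher on array 1, 145.5-fold and 202.8-fold higher on array 2, and 112.3-fold and 113.7-fold higher on array 3. The number of arrays limits the precision of the ratios.

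The comparison of knockout with wild type asked which transcripts differ when mecA is lost. The transcripts that rose most belonged to a run of 9 tags with consecutive numbers, among them STER_1840 and STER_1838. Averaged over the 9 tags, the log2 ratio of knockout to wild type was 4.85 ± 1.13 (SD, n = 2 biological replicates), a 28.8-fold higher signal in the knockout, and the single tags ranged from 1.76 to 5.85. The transcripts that fell most belonged to a run of 8 tags that holds STER_1367 and STER_1366. Their mean log2 ratio was -3.86 ± 0.92 (SD, n = 2), a 14.5-fold lower signal in the knockout, with single tags between -5.68 and -1.09. In all, 44 of the 1909 tags, or 2.30%, passed an adjusted p of 0.05 in limma's moderated test, 25 of them higher and 19 lower in the knockout. All 44 had 1 sign on all 3 arrays, as did 47.9% of all tested tags, and were well above background in both strains on all 3 arrays. Nearly every tested tag was: 2 were not detected in the knockout on at least 1 array, and 0 in the wild type.

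**Figure D1:**
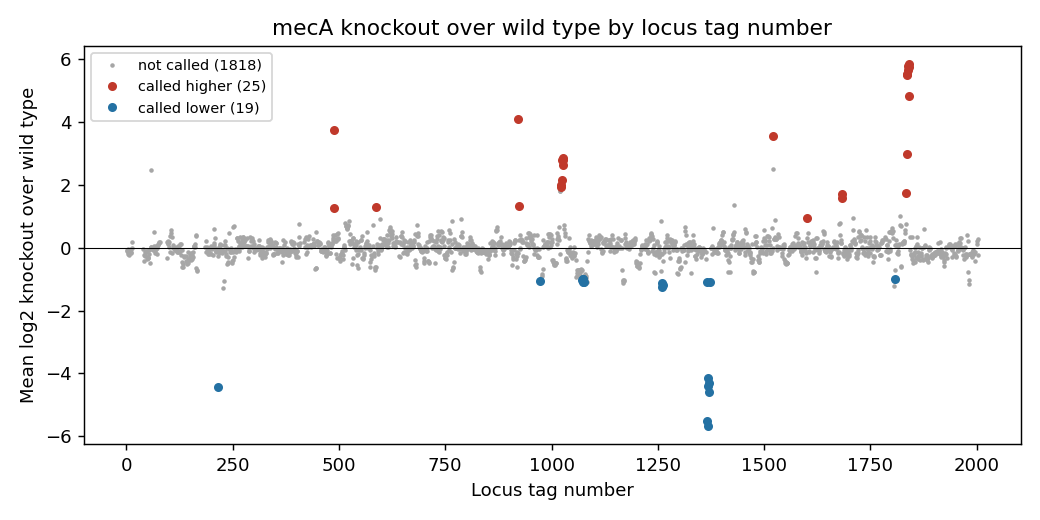
Mean log2 ratio of knockout to wild type (vertical axis) of each tested tag whose name holds digits alone, against the tag's number (horizontal axis). Grey points did not pass the test, and the red (25 higher) and blue (19 lower) points passed; the run of 9 raised tags averages 4.85 and the run of 8 lowered tags -3.86.

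STER_1840 had the highest log2 ratio, 5.85 ± 1.27 (SD, n = 2), or 57.7-fold higher in the knockout, with an adjusted p of 0.00173 in limma. Its ratio was 4.95 in biological replicate 1 and 6.75 in biological replicate 2. STER_1838 followed at 5.80 ± 1.17 (SD, n = 2), 55.5-fold higher, with an adjusted p of 0.00171 in limma. STER_1367 had the lowest ratio, -5.68 ± 0.90 (SD, n = 2), or 51.3-fold lower in the knockout, with an adjusted p of 0.00171 in limma. Its ratio was -5.04 in biological replicate 1 and -6.32 in biological replicate 2. STER_1366 stood at -5.52 ± 1.14 (SD, n = 2), 45.9-fold lower, also with an adjusted p of 0.00171 in limma. For these tags the change was several times the SD between the biological replicates. Limma moderated that SD by a spread pooled over all tags, an SD of 0.25 (log2). The pooled SD was below the SD of each named tag, so the adjusted p-values do not follow from the tags' own spread.

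Most of the other called tags also lay next to one another. Another 7 consecutive tags rose together, with a mean log2 ratio of 2.45 ± 0.49 (SD, n = 2) and single tags between 1.93 and 2.87. A run of 5 consecutive tags fell, with a mean log2 ratio of -1.04 ± 0.04 (SD, n = 2), as did a run of 3, with -1.19 ± 0.36 (SD, n = 2). The run of 5 gave -1.06 on array 1, -1.33 on array 2 and -0.69 on its dye swap, a gap that the averaging of arrays 2 and 3 keeps out of the SD. Of these 8 tags, 0 stayed called with a background offset of 0 or with median centring in place of loess, which called 20 higher and 10 lower tags in all, and 1 stayed called without array 2. The 5 runs of 3 or more called tags held 32 of the 44. There were also 3 neighbouring pairs that rose, with mean log2 ratios of 2.52 ± 0.92, 2.71 ± 1.01 and 1.65 ± 0.66 (SD, n = 2 each), of which 0 tags stayed called with an offset of 0. The remaining 6 called tags had no called neighbour, 3 of them higher and 3 lower in the knockout. The lowest of these single tags had a log2 ratio of -4.42 ± 1.87 (SD, n = 2) and the highest 3.56 ± 1.78 (SD, n = 2). The 16 tags called with an offset of 0 all lay in runs of 3 or more, so none of these single tags stayed called. The runs were defined after the values were seen.

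**Figure D2:**
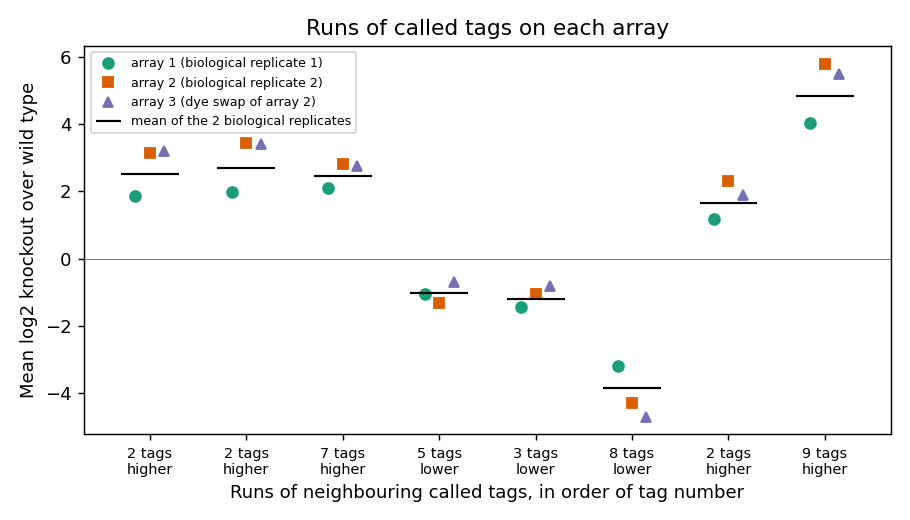
Mean log2 ratio of knockout to wild type (vertical axis) of the 8 runs of 2 or more neighbouring called tags (horizontal axis, in order of tag number), one symbol for each of the 3 arrays and a bar for the mean of the 2 biological replicates. Every run kept its sign on all 3 arrays, and the run of 9 raised tags gave 4.05 on array 1, 5.81 on array 2 and 5.49 on array 3.

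Of the called tags, 16 were at least 4-fold higher and 7 at least 4-fold lower, and 8 were at least 16-fold higher and 7 at least 16-fold lower. Counted without a test, 33 tags differed at least 2-fold in the same direction on each array, 26 higher and 7 lower, and 31 of the 33 were also called. On arrays 2 and 3 alone, where fewer arrays had to pass, 34 tags were higher and 38 lower by this count. At an unadjusted limma p of 0.05, 278 tags passed, where 95.45 were expected by chance.

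The ratios of the 3 arrays were compared across the 1909 tags, which are not independent replicates. Pearson's r was 0.92 between array 2 and its dye swap, 0.76 between arrays 1 and 2, and 0.66 between arrays 1 and 3. Among the 1865 tags that were not called, these values were 0.76, 0.43 and 0.20. The 23 called tags with a change of 4-fold or more all had a log2 ratio nearer 0 on array 1 than in biological replicate 2.

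**Figure D3:**
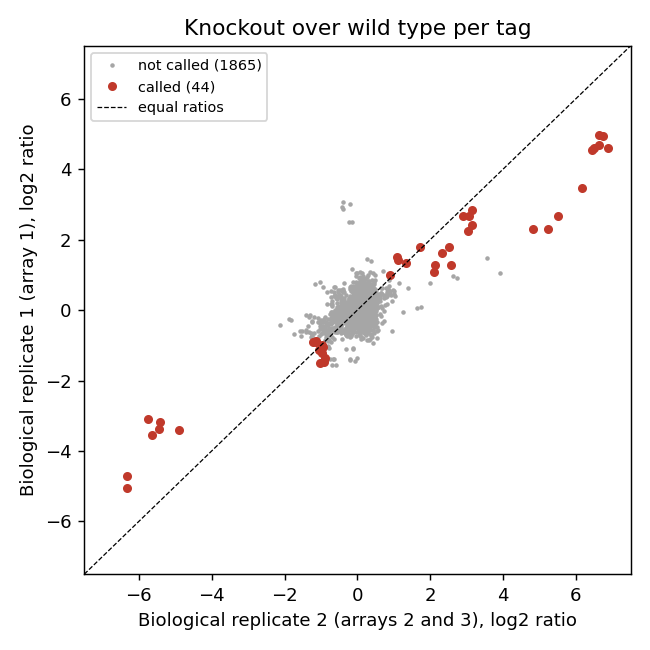
Log2 ratio of knockout to wild type of each tag in biological replicate 1 (vertical axis, array 1) against biological replicate 2 (horizontal axis, mean of arrays 2 and 3), with the 44 called tags in red and a dashed line of equal ratios. The 23 tags called at 4-fold or more lie nearer 0 on the vertical axis than on the horizontal one.

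With arrays 1 and 2 alone, limma called 0 tags, with 2.51 prior degrees of freedom against 5.0 and 277 tags at an unadjusted p of 0.05, while STER_1840 stood at 5.98 and STER_1367 at -5.35. With a dye term over the 3 arrays, a fit that treats the dye swap as independent RNA, limma called 5 tags. With a background offset of 0 it called 16. The 4 named tags, too far from 0 to change sign easily, kept their direction in both. With the dye term, however, STER_1840 and STER_1838 lost their call, at an adjusted limma p of 0.0737. Of the run of 9 raised tags, 8 stayed called with an offset of 0 and 1 with the dye term. For the run of 8 lowered tags these counts were 3 and 2, and for the run of 7 raised tags 5 and 2. The p-values of the main fit rest on the spread between 2 biological replicates, moderated by a spread pooled over all tags. That pooled spread carried 5.0 degrees of freedom, against 1 from the tag itself. Since biological replicate 1 has no dye swap, both the mean ratio and the spread between replicates also hold differences of dye and array. On arrays 2 and 3, the part of the ratio that turned with the dyes exceeded 0.5 (log2) in size for 18 tags. It exceeded 1 for 0 tags.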

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

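The 200 E1A control spots, which are outside the comparison of strains, stood well above background in 79.5% of channel readings on array 1, 81.2% on array 2 and 56.0% on array 3. The 77 negative control spots did so in 2.60% on each array. These spots drew attention because they carried signal that no comparison used; no explanation was tested.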

How the results depend on the processing

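The fit with a slide term and the counts of tags in runs were added after the data were seen. The count of 44 calls stayed within 1.5 times under 8 of 14 alternatives with all arrays, including median centring (20 higher, 10 lower). The 4 named tags, picked as extremes, kept direction under the 11 or 12 alternatives that moved their ratio, some lacking an array. Ratios that far from 0 could hardly change sign, so the kept direction is no check of these tags. Both tallies omit Aquantile (same ratios) and the deposited table (processed signals again). Without replicate 3 the named tags stood at 5.98 (both raised tags), -5.35 and -5.23 (log2) with adjusted p of 0.0661 to 0.133, and with a dye term the raised pair at 6.23 and 6.12 with 0.0737. Called tags numbered 16 with an offset of 0 (13 higher, 3 lower; 16 in runs of 3 or more), 102 without normalization within arrays (95 higher and 7 lower, against 25 and 19; 32 shared), where the median ratio of all tags moved to 0.58, 5 with a dye term (0 in runs), 134 with the arrays counted as 3 replicates (51 higher, 83 lower; 88 in runs), 107 with a slide term (47 higher, 60 lower; 78 in runs) and 278 at an unadjusted p of 0.05 (115 higher, 163 lower; 177 in runs). The counts of 134, 107 and 5 (dye term) come from fits that treat the dye swap as independent RNA. The causes of the other shifts were not tested.

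Leaving out 1 array gave 0 to 33 called tags (0 to 23 in runs); limma's 0 came from arrays 1 and 2, with 277 tags at an unadjusted p of 0.05. Arrays 1 and 3, on 1 slide, gave 33 (24 higher, 9 lower), all among the 44. Tags at least 2-fold the same way on every array numbered 34 to 72 when 1 array was left out. Fewer arrays then had to pass, so this count could not fall below the 33 of all 3 arrays. The 72 (34 higher, 38 lower) came from arrays 2 and 3, which allow no test. Arrays 1 and 2 gave 26 higher and 17 lower. With 3 arrays limma gave no correlation, hence no value, for a random block of biological replicate or slide. Alternatives for gene lists and the genes beside mecA were not run, for lack of gene names. Array 1 had the lowest signal over background, 32.3-fold in green.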

Other observations

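Of the tests in this part, the shuffling of called tags, the mixing of RNA, the size of the response in replicate 1 and those of the r tags were chosen after the results were seen.

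With a looser definition, a change of at least 1.5-fold in the mean and 1 sign on all 3 arrays, 68 tags were higher and 105 lower in the knockout. They gave 7 runs of 5 or more consecutive tags, 3 higher and 4 lower, and 5 of these 7 hold called tags, 30 of the 73 tags in them. Of the 7 runs, 3 hold the strongly changed called runs. With neighbours added there were 10 tags at 4.44 ± 0.97 and 11 tags at 2.01 ± 0.60, and the called run of 8 tags stayed as it was at -3.86 ± 0.92 (mean log2 ratio, SD, n = 2 biological replicates each). The longest held 25 tags at -0.87 ± 0.18 (SD, n = 2), of which 5 were called, and another run of 8 lay at -0.93 ± 0.34 (SD, n = 2) with 1 called. The other 2 had no called tag: 6 tags at -1.0 ± 0.56 and 5 tags at 0.68 ± 0.24 (SD, n = 2 each), with lowest adjusted p-values in limma of 0.070 and 0.0897. The 6 tags gave -1.40 on array 1, -0.75 on array 2 and -0.46 on its dye swap. The 5 tags gave 0.51, 1.27 and 0.42, and the averaging of arrays 2 and 3 keeps the gap between them out of the SD.

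The called tags formed 30 neighbouring pairs with the same direction, where 10000 shuffled orders gave at most 5 (permutation p = 1e-04, the smallest they can give), so chance order is excluded. Spots of neighbouring called tags lay 0.98 times as far apart as spots of random tags, which argues against position on the array, and 0% of the called pairs held probes sharing 20 bases, against 0.28% of other neighbours, which argues against shared probe sequence. Among tags that were not called, neighbours also moved together across the genome, with a Spearman rho of 0.65 against 0.0057 at a distance of 20 tags (permutation p = 0.001, the smallest 1000 shuffles can give). A candidate explanation is that neighbouring genes share transcripts, a hypothesis found and tested on the same data.

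All 23 tags called at 4-fold or more had log2 ratios nearer 0 on array 1, where the log2 ratio was a median of 0.70 times that in biological replicate 2. The offset of the background correction does not account for it, since the median was 0.71 with an offset of 0. Mixing of each strain's RNA into the other, at most 3.03% and 3.20% by the most extreme tags, would leave a median shortfall of 0.36 (log2) over the 23 tags. Split by direction after that value was seen, the shortfall was 0.0082 among the 16 raised tags, though 4 of them fell short by over 0.5. Among the 7 lowered tags it was 0.73, which goes against mixing there. All of these 7 except 1 lie in the called run of 8 tags, however, so they are not independent. The cut of 0.5 was set after the results were seen, and the 0.36 over all 23 tags lies below it. Mixing is left open for the raised tags. Its limits come from these same 23 tags. A smaller response in the cultures of replicate 1 cannot be told apart from other features of array 1, since only that array holds their RNA.

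Of the 8 tags with an r before the number, 6 were picked for a log2 ratio above 2 on array 1. These 6 lay between 2.51 and 3.06 on array 1, 0.01 and 0.45 on array 2, and -1.05 and -0.67 on array 3. None was called, and the lowest of the 8 stood at 0.15 on array 1. With median centring in place of loess, red over green was 3.31, 1.98 and 2.22 on arrays 1, 2 and 3, whichever strain was red, so that knockout over wild type was -2.22 on array 3. The opposite sign on the dye swap argues against a change in the knockout in both biological replicates; a change in replicate 1 alone, where knockout over wild type was 3.31, cannot be told apart from features of array 1, since replicate 1 has no dye swap. The median percentile of brightness of these tags was 99.84 on array 1 and 99.87 on arrays 2 and 3. A dye bias of bright spots, which loess removed less on array 1, is a candidate explanation. The 4 tags with an A had medians of -1.40, 0.10 and -0.36 on the 3 arrays. The 32 tags with a t had medians of 0.40, -0.43 and -0.55.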
